A study of Mus musculus with 15 samples.

How the data were processed

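Sox9-EGFP or Ngn3-EGFP males were mated to CD1 females, and pancreata were taken from embryos or from Sox9-EGFP pups, per the labels' protocols. The tissue was dissociated with collagenase B, with trypsin where needed, and cells of high GFP signal were collected by FACS. GFP- cells were collected at p23 as well. The protocols name no gate against leukocytes, endothelial cells or dead cells. Per the same protocols, 20 ng of total RNA per reaction was amplified with the NuGEN Ovation system from poly(A) RNA, and 3.75 ug of cDNA was fragmented, biotinylated and hybridised to Affymetrix mouse gene arrays.

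The authors summarised the array signals to linear intensity values per probe set with PLIER in Affymetrix Expression Console 1.1, per the submitters' processing notes, and these values were used as deposited. Whether the arrays were normalised to each other at that step is not given in the sources used here. The table holds 35557 probe sets in 15 arrays, and each array's median intensity lay between 165.5 and 211.7. The PLIER values depend on all arrays processed together, and no raw signal was used here. No 2 arrays were identical.

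Of the probe sets 21789 named 1 gene, 1621 named several and 12147 named none, and those with 1 gene were analysed. Of these, 21698 were matched by the gene identifier printed in the platform annotation, 0 symbols had to be updated, and the others kept the symbol as printed. They covered 19939 genes, of which 998 had several probe sets, and the probe set with the highest mean over the 15 arrays stood for the gene. The array platform holds families of near-identical genes (trypsinogens, amylases, globins, histocompatibility genes) whose probe sets can respond to each other's transcripts, which was not tested. Genes above intensity 97.8, the 30th percentile of all values, in at least 3 arrays were kept, which left 16883.

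Values were transformed to log2(intensity + 16) without further normalization between arrays. All 15 arrays entered 1 limma fit with a mean per group and a moderated variance shared over genes. The contrasts were e15.5 against e10.5, p23 against e15.5 and p23 against e10.5 in Sox9-GFP+ cells, Ngn3-GFP+ against Sox9-GFP+ cells at e15.5, and Sox9-GFP+ against GFP- cells at p23. A gene was called at a Benjamini-Hochberg adjusted p of 0.05 within each contrast. Changes that differed between the e15.5 and p23 contrasts were tested as an interaction in the same fit. With 3 arrays against 3 the smallest p of an exact rank test is 0.1, so no such test could call a gene. A gene's groups were said not to overlap when all values of 1 group lay above all values of the other.

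A set of 26 gene lists, covering pancreatic cell types, signalling pathways and cell types a sort could carry along, was fixed before the data were examined. Each was tested with the limma function camera at a preset correlation of 0.01 between genes and again with the correlation estimated from the residuals, adjusted over the 130 tests. The 26 lists were also tested on the interaction, adjusted on their own. Genes were named by a rule. It took Sox9 and Neurog3, the 5 largest rises and 5 largest falls among called genes whose groups did not overlap and whose higher mean lay above the table median of 187.5, and up to 5 called members of each list by size of change. Genes with clone or predicted names were skipped. Other members of a list were named with their values where their lack of a change mattered.

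Alternatives planned beforehand were offsets of 1 and 64, quantile normalization, median centring, no filter and a filter at the median, the mean of all probe sets or every probe set alone, the 2 groups alone, a trended robust variance, array weights, the replicate number as a block, each array left out, and limma treat against a 1.5-fold change. Fits without the arrays with embryonic globin signal and without the Sox9-GFP+ p23 arrays with leukocyte signal were added after seeing the data.

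In a self-test, changes were planted in few genes of simulated arrays of the same design. The noise was independent between genes and equal in all groups, unlike that of the real arrays. The share recovered at 1.5-, 2- and 4-fold was 40.3, 88.1 and 98.5% from e10.5 to e15.5, 32.8, 79.1 and 97% from e15.5 to p23, and 32.8, 74.6 and 97% from e10.5 to p23. It was 37.3, 76.1 and 95.5% between the e15.5 sorts and 40.3, 74.6 and 97% between the p23 sorts. Between 4 and 10 genes per contrast were called falsely. A list of 30 genes shifted by 0.5 was called in each contrast and 0 of 20 random lists were. As the simulated genes were uncorrelated, this does not tell how often lists of correlated genes are called. The software was R 4.3.3 with limma 3.58.1, and Python 3.11.15 with numpy 2.4.6 and matplotlib 3.10.9.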

Results

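Sorted cells of the developing and young mouse pancreas were profiled on 15 gene expression arrays in 5 groups, with n = 3 arrays per group. The groups were Sox9-GFP+ cells at e10.5, e15.5 and p23, Ngn3-GFP+ cells at e15.5, and GFP- cells at p23. The labels state that multiple animals were pooled for each sort, so a p-value here measured the spread between such arrays and not between single animals. That spread was estimated per gene within all 5 groups together, so an error can differ from the spread of the groups compared. Sox9, for example, had an SD of 0.0222 in Sox9-GFP+ cells at e15.5 and 0.745 in GFP- cells. Arrays of a group correlated at 0.988 to 0.995 in Sox9-GFP+ cells at e15.5 and at 0.933 to 0.952 in Ngn3-GFP+ cells, the least alike group. Their number limits the precision of every change given below. Changes are differences of log2(intensity + 16), which understates the change of dim genes, and errors are standard errors from limma. The list tests assumed a small fixed correlation between genes. Mismatched splits of the same arrays, which keep part of the real difference, called up to 17 lists in 1 comparison. Each list is therefore given first by the number of its members that changed.

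The Sox9 transcript followed the Sox9 sort, and the Neurog3 transcript did not follow the Ngn3 sort at e15.5. Sox9 stood at log2 12.12, 11.93 and 11.84 in the 3 Sox9-GFP+ arrays at e10.5, at 12.14, 12.10 and 12.11 at e15.5, and at 11.62, 11.94 and 12.10 at p23. It stood at 11.21, 10.13 and 11.14 in Ngn3-GFP+ cells and at 10.08, 9.81 and 8.68 in GFP- cells. Neurog3 stood at 10.24, 9.9999 and 9.23 in Sox9-GFP+ cells at e10.5 and at 12.12, 11.82 and 11.66 at e15.5. Ngn3-GFP+ cells had Neurog3 values of 11.53, 11.75 and 12.21. At p23 the values were 5.13, 5.25 and 5.06 in Sox9-GFP+ cells and 5.05, 5.31 and 5.10 in GFP- cells, below the 30th percentile of the arrays, 97.8 in linear intensity.

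**Figure D1:**
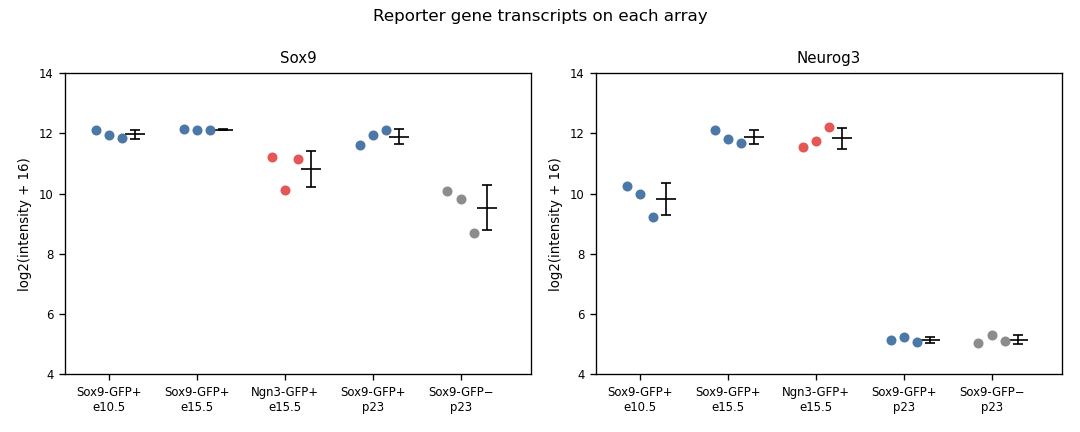
Sox9 (left) and Neurog3 (right) in log2(intensity + 16) on the vertical axis for the 5 sorted groups on the horizontal axis; each point is 1 array and bars are group means ± SD (n = 3). Sox9 was lowest in GFP- cells at p23 (mean 9.52) and Neurog3 was close to equal in Sox9-GFP+ (11.87) and Ngn3-GFP+ (11.83) cells at e15.5.

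Which genes changed in Sox9-GFP+ cells between e10.5 and e15.5? Over these days some of the fetal growth, liver and gut transcripts fell in Sox9-GFP+ cells, and most acinar and ductal ones rose. Acinar digestive enzyme genes such as Ctrb1 were among the largest gains of the genes named. Hormone transcripts were already present at e10.5, glucagon among them, and insulin and somatostatin transcripts increased. Stress-linked immediate early genes also increased between the sorts of the 2 stages.

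Between e10.5 and e15.5, limma called 4754 of 16883 genes at adjusted p of 0.05, 2060 higher and 2694 lower, with 690 up and 179 down by at least 2-fold. Sox9 was not called (0.15 ± 0.32, adjusted p = 0.741) and Neurog3 rose by 2.04 ± 0.23 (adjusted p = 3.23e-05). Of 31 acinar enzyme and secretory genes measured, 22 rose, 0 fell and the others were not called (22 and 0 adjusted over the list alone), with a median change of 2.27. The list test gave adjusted p = 1.33e-15, and adjusted p = 0.169 with an estimated correlation. Ctrb1, a chymotrypsinogen, rose by 6.90 ± 0.24 (n = 3 arrays per group), Pnliprp1, a pancreatic lipase-related protein, by 5.22 ± 0.22, and Cel, the bile salt-dependent lipase, by 4.65 ± 0.29. Of 28 acinar transcription factor and secretory machinery genes, 20 rose and 1 fell (21 and 2 adjusted over the list alone; adjusted p = 2.09e-13, and adjusted p = 0.169 with an estimated correlation). Among them were Cckar, the cholecystokinin receptor of acinar cells (4.34 ± 0.28), Bhlha15, which builds the secretory machinery (2.88 ± 0.21), and Rbpjl, a partner of Ptf1a (2.51 ± 0.27). Of 38 ductal markers 22 rose and 3 fell (24 and 3 adjusted over the list alone; adjusted p = 3.6e-09, and adjusted p = 0.267 with an estimated correlation). Cldn10, a tight junction protein, rose by 4.01 ± 0.34 and Dcdc2a, a doublecortin family gene, by 4.95 ± 0.20, and the transcription factor Onecut2 fell by 3.10 ± 0.18.

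Of 10 islet hormone genes measured at e10.5 and e15.5, 4 rose and 0 fell (5 and 0 adjusted over the list alone; adjusted p = 0.0229, and adjusted p = 0.412 with an estimated correlation). Ins2 rose by 3.39 ± 0.24 and Sst by 2.53 ± 0.46 (n = 3 arrays per group), whereas Gcg, already at 13.32 at e10.5, was not called (-0.71 ± 0.32, adjusted p = 0.107). Of 45 endocrine granule and exocytosis genes 12 rose and 3 fell (15 and 4 adjusted over the list alone; adjusted p = 0.00348, and adjusted p = 0.46 with an estimated correlation), among them Scg2, a secretogranin (2.49 ± 0.34). Of 14 liver and biliary markers 0 rose and 7 fell (0 and 8 adjusted over the list alone), with a median of -0.90 (adjusted p = 7.29e-05, and adjusted p = 0.035 with an estimated correlation). Fgg, a fibrinogen chain, changed by -3.65 ± 0.26. Of 21 fetal growth genes 2 rose and 10 fell (2 and 11 adjusted over the list alone; adjusted p = 0.00196, and adjusted p = 0.175 with an estimated correlation), with Lin28b, a repressor of let-7 maturation, at -4.53 ± 0.14. After median centring 2 rose and 4 fell. Of 17 gut and stomach epithelium markers 1 rose and 10 fell (1 and 10 adjusted over the list alone; median -0.55, adjusted p = 0.00196, and adjusted p = 0.348 with an estimated correlation), and 1 and 7 after median centring. Of 29 dissociation and immediate early genes 17 rose and 0 fell (20 and 1 adjusted over the list alone; adjusted p = 1.67e-12, and adjusted p = 0.149 with an estimated correlation), including Fos (3.33 ± 0.31) and Egr1 (3.15 ± 0.32), which respond to tissue handling as well as to growth factors. The largest falls named by rule were Nepn, a matrix proteoglycan (-6.40 ± 0.22), Fndc3c1 (-5.47 ± 0.18) and Cysltr2, a leukotriene receptor (-5.19 ± 0.42).

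The share of higher genes between e10.5 and e15.5 depended on the scaling of the arrays. It was 43.3% as deposited, 63% after quantile normalization, 73.9% after median centring and 58.2% with the dim gene filter at the median. The median of all genes moved from -0.05 to 0.12 with centring. The count was 1840 without e15.5 replicate 3, 2168 without e15.5 replicate 2, 1896 without e10.5 replicate 3 and 2179 without e10.5 replicate 2. It was 2718 after quantile normalization and 7149 when only these 6 arrays were fitted. Embryonic globin (Hbb-y, of a family whose probe sets can respond to each other) stood at 10.48, 11.20 and 6.05 at e10.5 and at 9.98, 5.93 and 6.35 at e15.5, and 2673 genes were called without the 3 arrays above 9, a fit that left 1 array at e10.5 and 2 at e15.5. The 2 groups did not overlap in 57.3% of the genes, where 10% is the share for groups that do not differ.

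Which genes changed in Sox9-GFP+ cells between e15.5 and p23? Most endocrine granule, cell cycle and fetal growth genes were lower in Sox9-GFP+ cells at p23 than at e15.5. Ductal genes and genes of antigen presentation and epithelial immune defence were higher. The mean of the immune defence list was no lower in GFP- cells of p23. Acinar enzyme transcripts rose further. Transcripts of leukocytes and endothelial cells and the immediate early genes were also higher at p23.

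Between e15.5 and p23, limma called 9714 genes, 5184 higher and 4530 lower, with 825 up and 1370 down by at least 2-fold. Sox9 was not called (-0.23 ± 0.32, adjusted p = 0.55) and Neurog3 fell by 6.72 ± 0.23 (adjusted p = 9.19e-11). Of 45 endocrine granule and exocytosis genes 1 rose and 37 fell (2 and 38 adjusted over the list alone; median -2.33, adjusted p = 1.33e-15, and adjusted p = 0.122 with an estimated correlation). Abcc8, a subunit of the potassium channel that gates insulin release, changed by -4.28 ± 0.20 and Pcsk1, a prohormone convertase, by -4.18 ± 0.29 (n = 3 arrays per group). Of 32 endocrine transcription factors 6 rose and 21 fell (6 and 21 adjusted over the list alone; adjusted p = 5.8e-08, and adjusted p = 0.122 with an estimated correlation), among them Insm1 (-5.08 ± 0.23) and Pax6 (-4.97 ± 0.21), both needed for islet cell differentiation. Of 10 hormone genes 0 rose and 8 fell (0 and 8 adjusted over the list alone; adjusted p = 4.28e-05, and adjusted p = 0.175 with an estimated correlation), with Gcg at -3.89 ± 0.32. Of 49 cell cycle genes 0 rose and 44 fell (0 and 44 adjusted over the list alone; median -1.41, adjusted p = 7.85e-16, and adjusted p = 0.236 with an estimated correlation), with the mitotic kinase Plk1 at -2.84 ± 0.28 and Rrm2, a ribonucleotide reductase subunit, at -2.28 ± 0.23. Of 21 fetal growth genes 1 rose and 17 fell (1 and 17 adjusted over the list alone; median -2.18, adjusted p = 4.84e-09, and adjusted p = 0.0418 with an estimated correlation), with Igf2, a fetal growth factor, at -5.08 ± 0.41 and the imprinted gene Peg10 at -5.36 ± 0.23.

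Of 38 ductal markers measured at e15.5 and p23, 24 rose and 2 fell (25 and 2 adjusted over the list alone; median 1.43, adjusted p = 8.15e-08, and adjusted p = 0.285 with an estimated correlation). Cp, the ferroxidase ceruloplasmin, rose by 5.96 ± 0.49, Cftr, the chloride channel of ductal secretion, by 3.69 ± 0.40 and Anxa3, an annexin, by 4.32 ± 0.30 (n = 3 arrays per group). Of 34 ductal fluid and bicarbonate transport genes 13 rose and 6 fell (13 and 6 adjusted over the list alone; adjusted p = 0.0348, and adjusted p = 0.523 with an estimated correlation), with Car4, a membrane carbonic anhydrase, at 2.86 ± 0.25. Of 31 antigen presentation and epithelial immune defence genes 26 rose and 1 fell (26 and 1 adjusted over the list alone; median 1.83, adjusted p = 6.58e-12, and adjusted p = 0.0199 with an estimated correlation). They included Reg3a (7.45 ± 0.15) and Reg3b (7.20 ± 0.15), antibacterial lectins of closely related sequence, and Lcn2, which binds bacterial siderophores (3.55 ± 0.33). The immune defence list had means of 9.86, 9.75 and 9.81 in the Sox9-GFP+ arrays at p23. In GFP- arrays of that age its means were 9.89, 10.01 and 9.97, so this level was not particular to Sox9-GFP+ cells. Of 31 acinar enzyme and secretory genes 28 rose and 1 fell (28 and 1 adjusted over the list alone; median 4.19, adjusted p = 3.92e-14, and adjusted p = 0.175 with an estimated correlation), with Gp2, a zymogen granule membrane protein, at 7.10 ± 0.19 and Reg2 at 8.13 ± 0.15. The acinar transcription factor and secretory machinery genes moved both ways, 10 up and 8 down (test adjusted p = 0.579), and the acinar regulator Ptf1a fell by 1.85 ± 0.31. Of 29 dissociation and immediate early genes 27 rose and 0 fell (27 and 0 adjusted over the list alone; adjusted p = 1.41e-10, and adjusted p = 0.169 with an estimated correlation), with the heat shock gene Hspa1a at 4.80 ± 0.40. The regulators Pdx1 (-1.54 ± 0.21) and Nkx6-1 (-3.29 ± 0.29) fell, while 7 of 28 progenitor regulators rose and 11 fell.

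Of 25 leukocyte markers 20 rose and 1 fell between e15.5 and p23 (20 and 1 adjusted over the list alone; adjusted p = 1.49e-05, and adjusted p = 0.279 with an estimated correlation). Ptprc, the pan-leukocyte phosphatase, rose by 3.06 ± 0.43 and stood at 8.12, 10.64 and 10.09 in the 3 Sox9-GFP+ arrays at p23. Of 20 endothelial markers 17 rose and 1 fell (17 and 1 adjusted over the list alone; adjusted p = 0.00103, and adjusted p = 0.298 with an estimated correlation). With quantile normalization 12 leukocyte and 7 endothelial markers rose. Genes called higher were 53.4% as deposited, 39.1% after median centring and 42.1% with the filter at the median, and centring moved the median of all genes from 0.05 to -0.12. The groups did not overlap in 72.7% of the genes, where 10% is the share for groups that do not differ.

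Which genes changed in Sox9-GFP+ cells across the whole interval, from e10.5 to p23? Acinar, ductal and immune defence genes were higher at p23 than at e10.5. For the immune defence list, the mean in GFP- cells of p23 was no lower. Endocrine granule genes were below their e10.5 level at p23. Sox11 and the neurofilament gene Nefl were among the 5 largest falls named by rule.

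Between e10.5 and p23, limma called 6916 genes, 2981 higher and 3935 lower, with 1356 up and 1262 down by at least 2-fold. Sox9 was not called (-0.08 ± 0.32, adjusted p = 0.878) and Neurog3 fell by 4.68 ± 0.23 (adjusted p = 1.63e-09). The largest rises named by rule were Cpb1, a carboxypeptidase (8.42 ± 0.69), Zg16, a zymogen granule protein (8.19 ± 0.72), Try4, a trypsinogen (7.85 ± 0.91), Reg2 (7.80 ± 0.15) and Cel (7.66 ± 0.29), with n = 3 arrays per group. The largest falls were Sox11, a transcription factor of progenitors and neurons (-7.55 ± 0.35), Nepn (-7.21 ± 0.22), Nefl, a neurofilament (-6.97 ± 0.61), Isl1, an islet and mesenchymal regulator (-6.10 ± 0.27), and Zdbf2, an imprinted gene (-6.09 ± 0.23). Of 38 ductal markers 29 rose and 3 fell (29 and 3 adjusted over the list alone; median 2.75, adjusted p = 3.18e-15, and adjusted p = 0.169 with an estimated correlation), with Cp at 6.76 ± 0.49 and Cftr at 4.55 ± 0.40. Of 31 immune defence genes 27 rose and 0 fell (28 and 0 adjusted over the list alone; median 2.28, adjusted p = 2.18e-17, and adjusted p = 0.011 with an estimated correlation). Of 21 fetal growth genes 0 rose and 16 fell (0 and 16 adjusted over the list alone; median -3.32, adjusted p = 9.2e-13, and adjusted p = 0.0199 with an estimated correlation), with Igf2bp1, an RNA-binding protein of fetal tissue, at -5.50 ± 0.34. Of 45 granule and exocytosis genes 3 rose and 36 fell (3 and 36 adjusted over the list alone; median -1.79, adjusted p = 3.01e-13, and adjusted p = 0.15 with an estimated correlation). Of 31 acinar enzyme and secretory genes 30 rose and 1 fell (30 and 1 adjusted over the list alone; median 6.77, adjusted p = 2.07e-27, and adjusted p = 0.0911 with an estimated correlation). Of 49 cell cycle genes 1 rose and 43 fell (1 and 43 adjusted over the list alone; median -1.16, adjusted p = 1.07e-12, and adjusted p = 0.267 with an estimated correlation), with Bub1b, a spindle checkpoint kinase, at -2.48 ± 0.26.

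Of 29 dissociation and immediate early genes 26 rose and 0 fell from e10.5 to p23 (26 and 0 adjusted over the list alone; median 3.52, adjusted p = 3.07e-19, and adjusted p = 0.0902 with an estimated correlation), with Egr2 at 5.09 ± 0.30 (n = 3 arrays per group). Of 25 leukocyte markers 14 rose and 0 fell (14 and 0 adjusted over the list alone; adjusted p = 9.17e-06, and adjusted p = 0.267 with an estimated correlation). The groups did not overlap in 50.9% of the genes (10% for groups that do not differ), and 3559 genes were called without the 3 arrays with Hbb-y above 9. That fit left 1 array at e10.5.

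How did Ngn3-GFP+ cells differ from Sox9-GFP+ cells at e15.5? Ngn3-GFP+ cells were poorer in cell cycle transcripts and richer in transcripts of secretory granules and hormones. Some acinar regulators and immediate early genes were lower in them. The endocrine regulators Neurog3, Pdx1 and Nkx6-1 were not called between the sorts, and genes of gut epithelium were higher in Ngn3-GFP+ cells.

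Between the e15.5 sorts, limma called 7034 genes, 3933 higher and 3101 lower in Ngn3-GFP+ cells, with 127 up and 749 down by at least 2-fold. Sox9 was lower (-1.29 ± 0.32, adjusted p = 0.00803) and Neurog3 was not called (-0.04 ± 0.23, adjusted p = 0.911). Of 49 cell cycle genes 0 were higher and 44 lower (0 and 44 adjusted over the list alone; median -1.30, adjusted p = 9.3e-22, and adjusted p = 0.169 with an estimated correlation). Gmnn, which restrains replication licensing, changed by -2.08 ± 0.28, the checkpoint kinase Bub1 by -2.05 ± 0.24 and Cdk1 by -2.04 ± 0.31 (n = 3 arrays per group). Of 45 granule and exocytosis genes 27 were higher and 1 lower (28 and 2 adjusted over the list alone; median 0.62, adjusted p = 1.75e-07, and adjusted p = 0.267 with an estimated correlation). Glp1r, the incretin receptor, was higher by 2.90 ± 0.23, Sytl4, a granule docking protein, by 2.89 ± 0.17, Slc30a8, the zinc transporter of insulin granules, by 2.84 ± 0.48 and G6pc2, an islet glucose-6-phosphatase, by 2.65 ± 0.41. Of 10 hormone genes 5 were higher and 0 lower (6 and 0 adjusted over the list alone; adjusted p = 0.00297, and adjusted p = 0.285 with an estimated correlation), with Npy at 3.80 ± 0.23, Iapp, the islet amyloid peptide, at 1.54 ± 0.30 and Ins2 at 0.96 ± 0.24. Of 32 endocrine transcription factors 11 were higher and 2 lower (11 and 2 adjusted over the list alone; adjusted p = 0.00577, and adjusted p = 0.332 with an estimated correlation), among them Mlxipl, which responds to glucose (1.40 ± 0.23), and Pax6 (0.87 ± 0.21). Pdx1 (0.41 ± 0.21, adjusted p = 0.126) and Nkx6-1 (0.16 ± 0.29, adjusted p = 0.668) were not called.

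Of 28 acinar transcription factor and secretory machinery genes 0 were higher and 10 lower in Ngn3-GFP+ cells at e15.5 (0 and 9 adjusted over the list alone; adjusted p = 0.000893, and adjusted p = 0.435 with an estimated correlation). Ptf1a, the acinar and early progenitor regulator, changed by -2.14 ± 0.31 and Cckar by -2.33 ± 0.28 (n = 3 arrays per group). Of 31 acinar enzyme and secretory genes 2 were higher and 9 lower (2 and 9 adjusted over the list alone; adjusted p = 0.017, and adjusted p = 0.608 with an estimated correlation), with Cpa1 at -1.72 ± 0.26. Of 29 dissociation and immediate early genes 2 were higher and 11 lower (2 and 11 adjusted over the list alone; adjusted p = 0.000268, and adjusted p = 0.356 with an estimated correlation), led by Egr2 (-4.70 ± 0.30) and Nr4a1 (-3.08 ± 0.23). Atf3 was also lower (-2.71 ± 0.79), a call that ended without Sox9-GFP+ replicate 2 (-2.45) or 3 (-2.46). It stood at 9.13, 4.78 and 8.39 in the 3 Ngn3-GFP+ arrays, and the difference was -1.38 without Ngn3-GFP+ replicate 2. Of 35 Notch pathway genes 9 were higher and 10 lower as deposited, 6 and 11 after quantile normalization, and 2 and 11 after median centring. Nrarp (-1.90 ± 0.21), Hes1 (-1.42 ± 0.23) and Jag1 (-0.90 ± 0.16), which report or send the Notch signal, were lower. Id1 (-2.23 ± 0.28) and Id3 (-2.19 ± 0.38), targets of BMP, were lower as well, while of 38 TGF-beta and BMP pathway genes 6 were higher and 6 lower as deposited, 1 and 6 after quantile normalization, and 3 and 12 after median centring. Of 17 gut and stomach epithelium markers 14 were higher and 0 lower (15 and 0 adjusted over the list alone; adjusted p = 5.66e-05, and adjusted p = 0.267 with an estimated correlation), with Isx, an intestinal homeobox gene, at 0.74 ± 0.16. The intestinal pentraxin Mptx1, among the 5 largest rises (3.46 ± 1.01), stood at 5.30, 8.77 and 11.48 in the 3 Ngn3-GFP+ arrays, and its difference was 1.98 without replicate 3. Its call ended when only these 6 arrays were fitted (3.46) and without the arrays with embryonic globin (3.55).

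Of 20 endothelial markers 10 were higher and 1 lower in Ngn3-GFP+ cells (10 and 1 adjusted over the list alone; adjusted p = 0.00406, and adjusted p = 0.356 with an estimated correlation), but 0 were higher and 1 lower after quantile normalization. Of 25 leukocyte markers 7 were higher and 1 lower (6 and 1 adjusted over the list alone; adjusted p = 0.0166, and adjusted p = 0.523 with an estimated correlation), and 3 and 1 after quantile normalization. Among gut markers 6 were higher and 0 lower after quantile normalization, fewer than as deposited. Of the called genes 55.9% were higher as deposited, 42.1% after quantile normalization, 28% after median centring and 40.7% with the filter at the median. Centring moved the median of all genes from 0.04 to -0.16. The count of called genes was 3757 without Sox9-GFP+ e15.5 replicate 3, 4644 without replicate 2 and 4056 after quantile normalization. The groups did not overlap in 56.2% of the genes, where 10% is the share for groups that do not differ.

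How did Sox9-GFP+ cells differ from GFP- cells at p23? Sox9-GFP+ cells carried the ductal programme, with its channels, and primary cilium genes were higher in them than in GFP- cells. Progenitor regulators and FGF and EGF receptor signalling genes were higher in them than in GFP- cells. Wnt pathway genes were also higher. The means of the cilium and Wnt lists in Sox9-GFP+ cells at p23 were near those at e15.5, and GFP- cells had the lowest. Acinar regulators were lower in Sox9-GFP+ cells, while most digestive enzymes were not called. The largest differences among the genes named by rule were lymphocyte genes, higher in GFP- cells.

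At p23, limma called 6077 genes, 3622 higher and 2455 lower in Sox9-GFP+ cells, with 1534 up and 949 down by at least 2-fold. Of the called genes 59.6% were higher as deposited, 55.2% after quantile normalization and 50.6% after median centring. Sox9 was higher by 2.37 ± 0.32 (adjusted p = 3.45e-05) and Neurog3 was not called (-0.01 ± 0.23, adjusted p = 0.984). Of 38 ductal markers 32 were higher and 1 lower (32 and 2 adjusted over the list alone; median 2.35, adjusted p = 3.92e-14, and adjusted p = 0.175 with an estimated correlation). Krt7, a keratin of simple epithelia, was higher by 3.45 ± 0.19, Krt19 by 2.88 ± 0.22, Wfdc2, a secreted protease inhibitor, by 3.96 ± 0.25 and Cftr by 4.23 ± 0.40 (n = 3 arrays per group). Of 45 primary cilium genes 29 were higher and 1 lower (32 and 2 adjusted over the list alone; median 0.73, adjusted p = 7.55e-09, and adjusted p = 0.122 with an estimated correlation). Pkhd1, the fibrocystin gene mutated in recessive polycystic kidney disease, was higher by 4.09 ± 0.31, Dync2li1, of the ciliary dynein, by 2.85 ± 0.24 and Ift81, of the intraflagellar transport complex, by 2.64 ± 0.15. The cilium list had means of 8.71, 8.81 and 8.97 in the Sox9-GFP+ arrays at p23 and 8.84, 8.94 and 8.86 at e15.5. In GFP- arrays the list means were 7.83, 7.84 and 7.86. Of 34 fluid and bicarbonate transport genes 20 were higher and 2 lower (21 and 2 adjusted over the list alone; adjusted p = 8.32e-05, and adjusted p = 0.267 with an estimated correlation), with Slc4a4, the sodium bicarbonate cotransporter, at 2.88 ± 0.24. Of 28 pancreatic progenitor regulators 18 were higher and 4 lower (18 and 4 adjusted over the list alone; adjusted p = 0.000185, and adjusted p = 0.267 with an estimated correlation), among them Prox1 (4.01 ± 0.18), Onecut1 (3.15 ± 0.19), Gata6 (2.79 ± 0.17) and Nkx6-1 (1.94 ± 0.29).

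Of 30 FGF and EGF receptor signalling genes at p23, 18 were higher and 3 lower in Sox9-GFP+ cells (19 and 3 adjusted over the list alone; adjusted p = 8.07e-05, and adjusted p = 0.169 with an estimated correlation). Fgfr2, the receptor of mesenchymal FGF10, was higher by 4.01 ± 0.23 and Erbb4, a neuregulin receptor, by 3.26 ± 0.34 (n = 3 arrays per group). Of 43 Wnt pathway genes 26 were higher and 1 lower (28 and 1 adjusted over the list alone; adjusted p = 3.22e-05, and adjusted p = 0.126 with an estimated correlation). Tcf7l2, an effector of the pathway, was higher by 1.90 ± 0.13, and Lef1, which T cells also express, changed by -4.37 ± 0.14. The Wnt list had means of 8.435, 8.52 and 8.48 in the Sox9-GFP+ arrays at p23 and 8.51, 8.46 and 8.48 at e15.5. In GFP- arrays the list means were 8.02, 7.85 and 7.84. Of 32 endocrine transcription factors 14 were higher and 0 lower (14 and 0 adjusted over the list alone; adjusted p = 0.00242, and adjusted p = 0.285 with an estimated correlation), with Glis3 at 2.79 ± 0.15, while the hormones Gcg (-1.26 ± 0.32, and -0.81 without Sox9-GFP+ replicate 1) and Ins2 (-0.98 ± 0.24) were lower. This transcription factor list had means of 7.68, 7.67 and 7.47 in Sox9-GFP+ arrays at p23 and 7.03, 6.79 and 6.87 in GFP- arrays. Both sets lay below its means in Sox9-GFP+ arrays at e15.5, 9.86, 9.85 and 9.63. Of 29 dissociation and immediate early genes 13 were higher and 0 lower (13 and 2 adjusted over the list alone; adjusted p = 0.0348, and adjusted p = 0.591 with an estimated correlation), with the YAP target Ccn1 at 2.21 ± 0.28. Ankrd1, another YAP target and the largest rise named by rule, was higher by 5.03 ± 0.29, followed by Snorc (4.60 ± 0.17) and Dcx, a microtubule protein (4.47 ± 0.26).

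Of 28 acinar transcription factor and secretory machinery genes 3 were higher and 18 lower in Sox9-GFP+ cells at p23 (3 and 18 adjusted over the list alone; median -1.22, adjusted p = 8.31e-07, and adjusted p = 0.285 with an estimated correlation). Ptf1a changed by -2.12 ± 0.31, Gnmt, a methyltransferase of acinar cells, by -2.57 ± 0.26 and Fkbp11, a chaperone of the secretory pathway, by -2.30 ± 0.28 (n = 3 arrays per group). Of 31 acinar enzyme and secretory genes 0 were higher and 5 lower (0 and 1 adjusted over the list alone; median -0.38, adjusted p = 0.0049, and adjusted p = 0.558 with an estimated correlation), and the differences of all 31 lay below 0 as deposited, from -1.85 to -0.01. The list median was -0.10 after quantile normalization, with 3 lower. Among those called were Serpini2, a pancreatic serpin (-0.93 ± 0.23), Amy1 (-1.85 ± 0.57) and Prss3 (-1.52 ± 0.47). The Amy1 call ended without Sox9-GFP+ replicate 1 (-1.73) or 3 (-1.72) and without GFP- replicate 1 (-1.81) or 2 (-1.83). The Prss3 call ended without Sox9-GFP+ replicate 3 (-1.47) and without GFP- replicate 1 (-1.45) or 2 (-1.45). The lipase Cel stood at 13.30, 13.38 and 13.19 in Sox9-GFP+ and at 13.67, 13.66 and 13.57 in GFP- arrays.

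Of 25 leukocyte markers 1 was higher and 21 lower in Sox9-GFP+ cells at p23 (1 and 21 adjusted over the list alone; median -2.77, adjusted p = 3.18e-15, and adjusted p = 0.122 with an estimated correlation). Ptprc stood at 14.28, 14.41 and 14.64 in the GFP- arrays and changed by -4.83 ± 0.43, and Coro1a, a leukocyte coronin, by -5.41 ± 0.20 (n = 3 arrays per group). The marker that was higher was Cd14 (2.45 ± 0.25). The largest falls named by rule were Ms4a1, a B cell antigen (-6.59 ± 0.20), Cd28, a T cell receptor (-6.43 ± 0.16), Ms4a4c (-6.27 ± 0.18), Gzma, a granzyme of cytotoxic cells (-5.98 ± 0.18), and Slamf6, a lymphocyte receptor (-5.85 ± 0.25). Of 20 endothelial markers 0 were higher and 11 lower (0 and 12 adjusted over the list alone; adjusted p = 3.9e-06, and adjusted p = 0.175 with an estimated correlation), with Pecam1 at -2.79 ± 0.21. Of 29 mesenchyme and stellate cell markers 2 were higher and 10 lower (3 and 11 adjusted over the list alone; adjusted p = 0.00292, and adjusted p = 0.391 with an estimated correlation). The groups did not overlap in 47.3% of the genes, where 10% is the share for groups that do not differ.

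**Figure D2:**
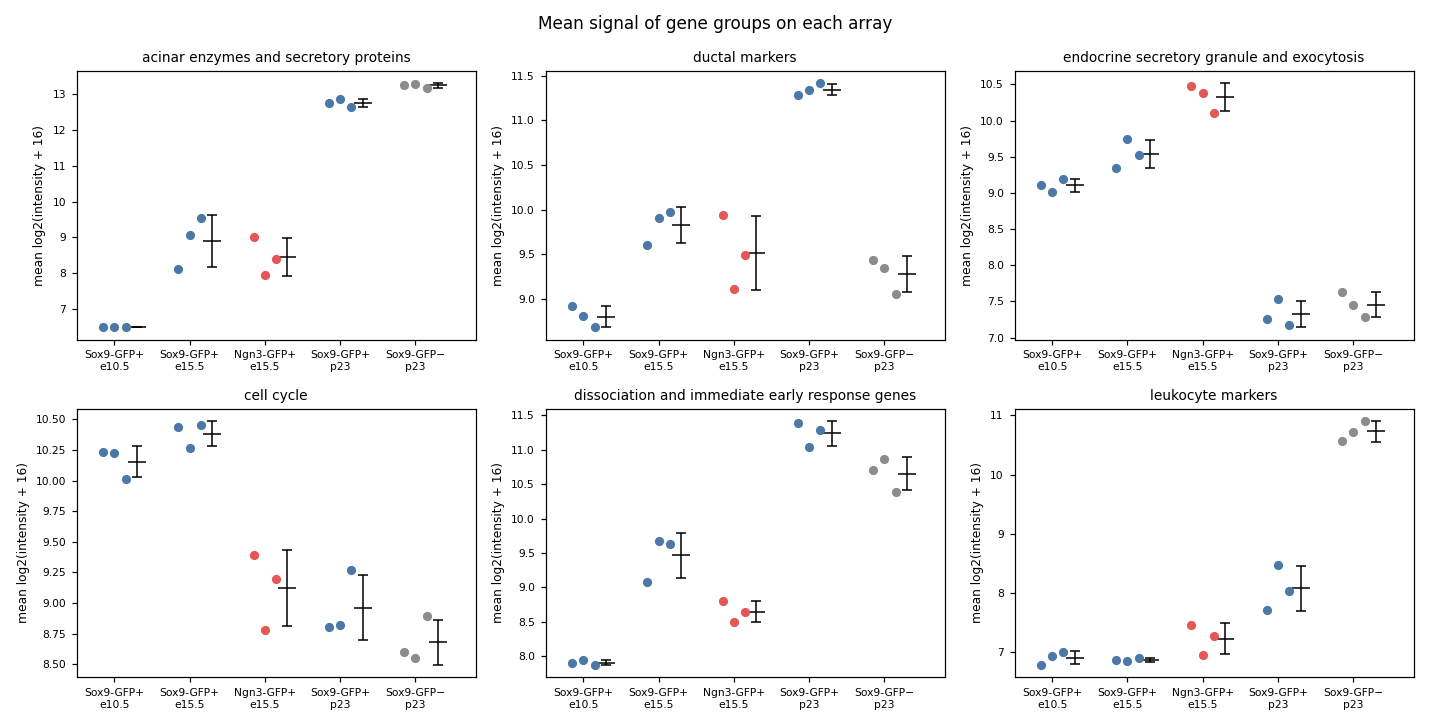
Mean log2(intensity + 16) of the measured members of 6 gene lists (vertical axis) for the 5 sorted groups (horizontal axis); each point is 1 array and black bars are group means ± SD (n = 3). Leukocyte markers stood at 10.56 to 10.90 in GFP- arrays at p23 against 7.72 to 8.47 in Sox9-GFP+ arrays of that age, and acinar enzymes at 13.18 to 13.29 against 12.64 to 12.87.

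Were Sox9-GFP+ cells set apart from the other sorted fraction by the same genes at e15.5 and at p23? Some genes were higher or lower in Sox9-GFP+ cells at both stages, and others differed in opposite directions. The other fraction was a different one at each stage, Ngn3-GFP+ cells at e15.5 and GFP- cells at p23. The acinar regulator Ptf1a lay on opposite sides at the 2 stages.

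Across both stages 832 genes were higher in Sox9-GFP+ cells at e15.5 and at p23, where 665.3 would be shared if the 2 sets were independent, and 320 were lower at both (571.9). Another 561 were higher at e15.5 and lower at p23 (450.9), and 382 were lower and then higher (843.8). Genes higher in Sox9-GFP+ cells at e15.5 thus exceeded independence in both directions at p23, and genes lower at e15.5 fell short in both. These counts therefore do not show a set of genes shared in direction. The e15.5 calls behind these counts depended on scaling. Genes higher in Ngn3-GFP+ cells numbered 3933 as deposited, 1709 after quantile normalization and 1752 after median centring. Genes lower in them numbered 3101, 2347 and 4496. The correlation of the 2 differences across genes was 0.0954, and genes are not independent replicates. Examples chosen after the values were seen were Ccn1 (2.11 at e15.5 and 2.21 at p23), Gmnn (2.08 and 2.01) and the cyclin Ccnd1 (1.84 and 2.89), higher at both, and Glp1r (-2.90 and -2.04), lower at both. Ptf1a was higher at e15.5 (2.14) and lower at p23 (-2.12), with an interaction of -4.26 ± 0.43 (adjusted p = 5.12e-06). The glucose transporter Slc2a2 was lower (-1.36) and then higher (2.99), with an interaction of 4.34 ± 0.33 (adjusted p = 3.29e-07).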

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

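The tests on leukocytes and endothelial cells in the GFP- sort and the tests on Neurog3 were chosen only after the result was seen; those on scaling at p23, on the acinar genes and on the splits were written beforehand.

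Leukocyte and endothelial genes were lower in Sox9-GFP+ than in GFP- cells at p23, although the series describes the GFP- fraction as acinar and endocrine cells. A hypothesis is that leukocytes were sorted with the GFP- cells, since no gate that would remove them is named. It predicted that most leukocyte markers would be highest in GFP- cells of all 5 groups, and 20 of 25 (80%) were, on the bound set for it. As 21 of the 25 had already been seen lower in Sox9-GFP+ cells at p23, the test nearly restates the pattern and cannot decide alone. The levels say more. The leukocyte list had means of 10.56 to 10.90 in GFP- arrays and 7.72 to 8.47 in Sox9-GFP+ arrays at p23. Ptprc stood at 14.28, 14.41 and 14.64 in GFP- arrays. This signal lay above the highest GFP- mean of an acinar enzyme, 13.90, though different probe sets need not reflect amounts of transcript alike. Of the 25 markers 1 was higher in Sox9-GFP+ cells. For these markers the values argue against a GFP- sort of acinar and endocrine cells alone. For endothelial cells 15 of 20 markers (75%) were highest in GFP- cells, which leaves the endothelial part open. Scaling of the arrays did not account for the lower leukocyte genes, because the leukocyte median was still -2.803 after quantile normalization. Whether the cells were resident in the pancreas or came from attached lymphoid tissue stays open and untested.

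Of 31 acinar enzymes 5 were called lower in Sox9-GFP+ than in GFP- cells at p23, Amy1 and Prss3 among them, with a median of -0.38 over the list, while acinar transcription factors and secretory machinery had a median of -1.22. Signals near the top of the scale could give this pattern. Acinar cells and their RNA carried into the Sox9-GFP+ sort could give it where such signals are compressed. Carry-over alone was predicted to lower enzymes and Ptf1a, Rbpjl and Bhlha15 alike. The highest GFP- mean of an enzyme was log2 13.90, with 6 other genes above it and 16.25 the highest value of the table, and the level at which each probe set saturates was not tested. The median difference of the dimmer enzymes lay 0.074 above that of the brighter ones and 1.5856 above the mean of Ptf1a, Rbpjl and Bhlha15. Both values met the bounds written beforehand against the explanations, top-of-scale signals for the first and carry-over alone for the second. The tests were set aside by a rule added after seeing that 0 of 31 enzymes had a GFP- mean between log2 9 and 12. No enzyme of middle brightness could therefore tell the explanations apart, and both stay open. Scaling did not account for the lower regulators, as the higher median of that list under quantile normalization or centring was -1.1492, and a true expression of enzyme genes in Sox9-GFP+ cells stays open and untested.

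Neurog3 was close to equal in Sox9-GFP+ and Ngn3-GFP+ cells at e15.5, although the series presents Ngn3-GFP+ cells as newly differentiated endocrine progeny. A hypothesis is that the Sox9-GFP+ sort held a diluted share of the same cells, which would lower Neurog3 as much as the granule genes. The granule genes called higher had a median of 0.93 against -0.04 for Neurog3, 4.23 standard errors of Neurog3 apart, but these genes had been picked for being higher and their own spread was left out. A test added after this value was seen took all 45 granule genes, with a median of 0.62 and an SD of 0.81. It put Neurog3 0.78 of the joint spread below them. That spread was of single granule genes and exceeded their median, so an equal Neurog3 could not have reached the bound against dilution. The test could not decide, and dilution stays open. Scaling did not hide a difference either, as the larger value under quantile normalization or centring was -0.2372. That Neurog3 peaks in cells that still carry Sox9-GFP, and that GFP outlasts the Neurog3 transcript in Ngn3-GFP+ cells, stays open and untested.

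Splits of the same 6 arrays into other groups of 3 asked whether any grouping would call as many genes. Between e10.5 and e15.5 the real grouping called 4754 and the highest other 1, between e15.5 and p23 9714 against 0, between e10.5 and p23 6916 against 0, between the e15.5 sorts 7034 against 14, and between the p23 sorts 6077 against 0. In each case 1 of 10 splits, the real one, reached the real count, and 10 splits are too few for a share under 0.05. Every other split kept 2 arrays of each group together and moved 1. The moved arrays brought the real difference into the spread, so low gene counts there followed from the design. For both stages jointly 1 of 100 splits reached the 1152 genes shared in direction, and the highest other had 1. Mismatched splits called almost no genes at either stage, so their overlap was near 0 from the outset and this count says nothing of a shared set. Beside independence, 832 genes were higher at both stages where 665.3 would be, and 320 were lower where 571.9 would be. Of genes that changed sides, 561 were higher and then lower where 450.9 would be. Another 382 were lower and then higher where 843.8 would be. These counts do not show a set shared in direction either. The gene lists behaved otherwise. The real grouping called 14, 14, 16, 10 and 13 lists in the order above, and the highest other split 14, 16, 14, 12 and 17, so that 2, 3, 1, 3 and 3 of 10 splits called as many, again too few for a share under 0.05. As these splits kept part of the real difference, they do not show how many lists would be called without one. The list calls at a preset correlation are therefore read only beside the counts of changed members.

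The difference between Sox9-GFP+ cells and the other fraction was tested for a change from e15.5 to p23 as an interaction (the p23 difference minus the e15.5 difference). Of the 26 lists 13 were called so and 0 with an estimated correlation, and 3 of the 13 are given here. These 3 were picked for also being called at each stage, in opposite directions for Sox9-GFP+ cells. Their interactions therefore follow in part from this choice. Of 31 acinar enzyme genes 0 had a higher and 13 a lower interaction, with a median of -0.9892 (adjusted p = 0.000409, and adjusted p = 0.469 with an estimated correlation). Of 28 acinar transcription factor and secretory machinery genes 1 was higher and 20 lower, with a median of -1.6052 (adjusted p = 1.15e-08, and adjusted p = 0.271 with an estimated correlation). Of 32 endocrine transcription factors 20 were higher and 0 lower, with a median of 0.7751 (adjusted p = 8.95e-05, and adjusted p = 0.271 with an estimated correlation). In addition 561 genes were higher at e15.5 and lower at p23, and 382 lower and then higher, and their interactions follow from these opposite calls. The other fraction was not the same at the 2 stages, and this difference of comparator was not separated from a change in Sox9-GFP+ cells.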

How the results depend on the processing

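All alternatives set beforehand were run, and most results of the named genes held. These genes were named mostly for called changes of large size, which favours stability. Over all genes, fewer calls held without Sox9-GFP+ e15.5 replicate 3. It left 1836 of the 4754 calls from e10.5 to e15.5 and 3747 of the 7034 between the e15.5 sorts. Of 9033 values for 630 named gene results under other settings, 8466 stayed the same, 560 were weaker and 7 reversed; of 3780 with 1 array left out, 3419, 354 and 7; of 69 called lists, 0 reversed. Counts for e10.5 to e15.5 moved from 4754 to 2718 (quantile), 7149 (2 groups alone), 425 (treat) and 2673 (without globin arrays), and between the e15.5 sorts from 7034 to 4056 (quantile) and 178 (treat). Treat gave 1615 for e15.5 to p23, 2199 for e10.5 to p23 and 2050 at p23, and e10.5 to p23 had 3559 without globin arrays. With 1 array left out the counts ranged from 1840 to 5952 (e10.5 to e15.5), 7512 to 9911 (e15.5 to p23), 5786 to 6741 (e10.5 to p23), 3757 to 6839 (e15.5 sorts) and 5055 to 5741 (p23); the cause was not tested. Without the p23 arrays with leukocyte signal, an alternative chosen after seeing the data like the globin one, 4278 genes were called at p23; single arrays left there were assumed to vary like the others. As a replicate block the counts were 3695, 9124, 6505, 6246 and 5737, but same-numbered arrays deviated together at r of -0.487 to 0.198, so the numbers do not pair. List calls fell from 69 to 5 with an estimated correlation. Reversed values, all but Hbb-y uncalled and near 0, were Sox9 from e10.5 to p23 at 0.0491 (quantile) and 0.0441 (without globin arrays), left-out range -0.1853 to 0.0549; Neurog3 between the e15.5 sorts at 0.035 (quantile), 0.0067 (weights) and 0.0898 (without globin arrays), range -0.2267 to 0.1154; Neurog3 at p23 at 0.0539 (weights), range -0.0615 to 0.0694; and Hbb-y from e10.5 to p23 at 0.0966 (without globin arrays), which follows from choosing the arrays by this gene. Signal over background limits dim genes, whose changes are understated.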

Other observations

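Signalling genes outside the duct programme also separated the p23 sorts. Of 38 TGF-beta and BMP pathway genes 19 were higher and 6 lower in Sox9-GFP+ cells, with the ligands Tgfb2 (3.30 ± 0.20) and Tgfb3 (2.06 ± 0.25) among them (n = 3 arrays per group). In the same cells both had risen from e15.5 (2.59 ± 0.20 and 3.21 ± 0.25). Of 35 Notch pathway genes 13 were higher and 5 lower at p23, including the target Hes1 (1.88 ± 0.23) and the receptor Notch2 (1.15 ± 0.20). The Hedgehog receptor genes Ptch1 (1.54 ± 0.13) and Smo (1.68 ± 0.12) were higher as well, and they were the 2 of 14 pathway genes that were. These lists were not called as a whole at p23.

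Glucagon transcript gave a high signal in the Sox9-GFP+ sort already at e10.5. Which cells of the sort held it was not tested, nor was the level at which its probe set saturates. Gcg stood at 13.29, 13.20 and 13.46 at e10.5, at 12.46, 12.68 and 12.69 at e15.5, and at 13.45, 13.50 and 13.33 in Ngn3-GFP+ cells. It stood at 7.80, 9.23 and 9.12 in Sox9-GFP+ cells at p23 and at 10.44, 10.19 and 9.33 in GFP- cells.

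Among genes chosen after the values were seen, Xist and the Y-linked Eif2s3y told the sex of the pooled animals at p23. Eif2s3y stood at 10.18, 4.27 and 10.64 in Sox9-GFP+ arrays and at 9.11, 10.15 and 4.32 in GFP- arrays. Xist stood at 12.49, 12.78 and 6.04 in the former and at 11.67, 11.01 and 12.0043 in the latter. Arrays of the same number therefore did not come from the same pool at p23 for numbers 2 and 3, and replicate 2 of Sox9-GFP+ cells and replicate 3 of GFP- cells showed female transcripts alone, while replicate 3 of Sox9-GFP+ cells showed male ones alone.

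Intestinal genes, also chosen after the values were seen, varied between the Ngn3-GFP+ arrays. Mptx1 stood at 5.30, 8.77 and 11.48, Fabp1 at 4.77, 7.04 and 8.15, and Lgals4 at 8.94, 9.40 and 10.20 in replicates 1, 2 and 3. Whether gut epithelium was taken along in the dissection was not tested.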
